A study of Mus musculus with 2 samples.

How the data were processed

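Liver sinusoidal endothelial cells (LSEC), the fenestrated cells that line the capillaries of the liver, came from 1 wild-type and 1 ob/ob mouse, both male and 8 weeks old. The ob/ob mouse carries a mutation of the leptin gene and becomes obese. Per the series' design text and the labels' protocols, livers were digested with collagenase, the cells were kept overnight in culture medium with serum, and total RNA was labelled with Cy3 after low-input amplification. Each RNA was hybridised to 1 array, so each group holds 1 array, and no replicate exists of either genotype.

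Per the file headers, the arrays are a 1-colour Agilent mouse design, number 026655, with 44397 spots and probe coordinates on mouse build mm9. The deposited scanner files hold spot intensity on a linear scale. Per the file headers and the submitters' processing notes, Agilent Feature Extraction 11.0.1.1 subtracted the background, removed spatial trends, gave spots at background a small substitute signal and flagged spots that were well above background, saturated or uneven; it did not scale the arrays to each other. A p-value that a spot equals its background stands in the deposited files, per the file headers, and was not used. The authors' deposited table of processed values holds 24868 features on a linear scale. Its values are the processed intensity divided by the 75th percentile of the same array, with a range of the ratio over features of 0.978% of its median for wild-type and 1.42% for ob/ob, they are not centred per gene, and all 24868 features were well above background on both arrays. The medians of its columns are 0.614 for wild-type and 0.648 for ob/ob, so scale, centring and direction were all settled from the files.

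The file of the ob/ob array carries signals written with 3 digits. In it 56 gene names differ from those of the other file, and 54 of them read as dates, as a spreadsheet program writes them. Probe names were identical at all 44397 spots, and gene names were taken from the wild-type file. Names were updated through accessions in a RefSeq gene table of assembly GRCm38.p6, used for names only. Of 39429 probes, 26049 were named through their main accession and 102 through another RefSeq accession. The name in the file was kept for 8552 probes and for 4 that match several genes, and 4722 have no gene name. Control spots were left out, leaving 43020 spots. Both arrays lie on 1 slide and were scanned on the same day, so no slide or scan separates the groups.

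The values used are log2 of the processed intensity minus log2 of the 75th percentile of the same array over non-control spots. That percentile was an intensity of 989 on the wild-type array and 1430 on the ob/ob array. Spots flagged as non-uniform (7 and 2) or as population outliers (143 and 119) were dropped, and no non-control spot was saturated. Spots of a probe were averaged, and a gene was represented by the probe with the highest mean over both arrays. A probe counted as measured where over 50% of its kept spots were well above background. Signals well above background numbered 25224 (58.6%) on the wild-type and 27873 (64.8%) on the ob/ob array. A gene measured on 1 array has only a bound on the other, taken as the brighter value over the higher of the dimmest measured signal (12.3 on the wild-type and 11.7 on the ob/ob array) and the signal of the dim probe itself. Such bounds are given as "at least N-fold". A gene was called not above background only where all its probes were.

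All differences are ob/ob minus wild-type on the log2 scale. With 1 array per group no test was run, no p-value is given, and the number of arrays limits the precision. Genes were counted where the difference was at least 2-fold. The spread available is technical. Over 259 probes spotted 10 times and measured on both arrays, the median SD of a single-spot difference was 0.08. The scanner's error model gave a median SD of 0.20 per gene. Different probes of 1 gene differed with an SD of 0.33 over 3694 genes with more than 1 measured probe. None of these holds the spread between mice or preparations.

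The 46 gene lists (1135 genes, of which 1128 are on the array) were fixed before the data were examined, as were the counts, the alternatives other than the one named below, and the rule for naming genes. For each list the median difference over members measured on both arrays is given with a 95% interval from order statistics (binomial), which describes the spread over members only. Its percentile among 10000 random lists of the same size, matched on mean level in 20 bins, is given as a description of these 2 arrays. A list with under 5 measured members has no percentile. Of the 45 lists with a percentile, 32 lay outside the central 95% of their random lists, where 2.25 would by chance. The random lists hold unrelated genes, so 2.25 applies only to lists whose members vary independently. The lists were chosen for this tissue and genotype and share members.

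Named are leptin and its receptor, and the 12 genes with the largest difference in each direction that were measured on both arrays, were at least 2-fold apart with the same sign under normexp background correction with quantile normalization, and had every measured probe of the same sign. Transcripts without a gene name and predicted or clone names were passed over, which skipped 3 among the largest lower differences and 0 among the higher. Another 13 of the largest lower differences were passed over because the probes or the other correction differed. Also named are the 6 largest bounds in each direction, the members of each list with the largest differences (up to 4), list members measured on 1 array with a bound of at least 2-fold, and the 3 brightest members of each cell type list. Some genes that the rule takes are not reported here. Genes named outside this rule were chosen after their values were seen. They are Stab1, Stab2, Lyve1, Cdh5, Pecam1, Icam1, Vcam1, Il6, Slc40a1, Nos3, Fasn, Nqo1, Hmox1, Sod3, Lrat, Phlda3, Cdkn1a, Mup3, the other Y-linked genes and those given for the alternative without patches.

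The alternatives were normexp background correction (offset 50, limma 3.58.1 in R 4.3.3) followed by quantile normalization or by the 75th percentile, scaling on the median of the array, quantile normalization of the processed intensity, centring the difference on the level by loess (span 0.3), the authors' deposited processed values, other filters on dim probes, the mean of all probes of a gene, other fold thresholds, random lists not matched on level, and another background flag. After the data were seen, 1 alternative was added, and its 4-fold limit was chosen after the neighbourhood medians had been looked at with several limits. It leaves out spots in patches, where a patch is a spot and its 12 nearest spots when the median difference of the 12 lies 4-fold or more from the median over all such neighbourhoods. It removed 75 of 43020 spots.

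The calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. They were tested on simulated arrays of the ob/ob against wild-type comparison over 19645 genes, with a noise SD of 0.15 per spot. All 150 genes planted at 3-fold or more were counted as at least 2-fold apart, as were 0 of 50 planted at 1.5-fold and 0 of 19405 unchanged genes. Genes were planted only above a set signal level, and every spot had the same noise. The simulation therefore covers neither dim planted genes nor the larger spread between probes of a gene (SD 0.33). A list of 40 genes planted at a log2 shift of 0.4 came out at 0.41. The 95% interval held the true median of 25 values in 95.7% of draws. Of 44 spots in a planted bright patch 41 were found, and 0 spots were called a patch when none was planted.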

Results

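The study set the RNA of LSEC from an obese, leptin-deficient ob/ob mouse against that of LSEC from a wild-type mouse, both 8 weeks old, after overnight culture. There was 1 mouse and 1 array per genotype, so every difference below compares 2 arrays and has no replicate check. Of 31880 genes and unnamed transcripts on the array, 18134 were measured on both arrays, 2168 on the ob/ob array only and 270 on the wild-type array only, while 11298 were above background on neither. Across the genes measured on both, the log2 signals of the arrays had a Pearson correlation of 0.983, which is across genes and not across replicates.

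Leptin, the hormone encoded by the mutated gene, was not well above background on either array, with signals of 2.97 in wild-type and 2.71 in ob/ob cells, so it checks nothing about the genotype of the samples. The leptin receptor Lepr was measured on both arrays, with signals of 123 and 144 and a log2 difference of -0.31. Its 3 measured probes all gave negative differences. Over the list of leptin and insulin response genes the median was -0.20 (95% interval -0.31 to 0.03, percentile 25.4 of its random lists, 0.01 after centring on the level), with 3 of 33 members at least 2-fold higher, 1 lower and 29 within 2-fold. Socs3, a feedback inhibitor of cytokine and leptin receptor signalling, was 1.34 higher, and Igfbp1, an insulin-repressed binding protein of insulin-like growth factors, was lower at -1.66.

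Between ob/ob and wild-type LSEC, 1054 genes were at least 2-fold higher and 415 at least 2-fold lower, together 8.10% of the genes measured on both arrays. The balance depended on the processing. Scaling on the array median, which moves every difference by -0.28, gave 765 and 976, and normexp with the 75th percentile gave 368 and 3818. The counts that follow use the main scaling. At 4-fold the counts were 328 and 36, and at 8-fold 95 and 3. The genes with the largest higher values included several known from macrophages and inflammation. Arg1, the arginase of the urea cycle and of alternatively activated macrophages, had a signal of 34.6 in wild-type and 4300 in ob/ob cells, a difference of 6.42 or 85.9-fold. Its probe lies on chromosome 10 at 24636194 to 24636253 (mm9). The cytokine Il1b was 6.07 higher (chromosome 2, 129190347 to 129190406) and the eosinophil chemokine Ccl24 5.40 higher (chromosome 5, 136046667 to 136046726). Pilra, a myeloid inhibitory receptor, had signals of 35.4 and 1640, with differences of 3.97 to 5.09 over its 3 measured probes. Adamdec1 was 4.79 higher, the formyl peptide receptor Fpr1 4.77, the cohesin subunit Smc1b 4.72, the macrophage phosphatidylserine receptor Timd4 4.63, the chemokine receptor Ccr7 4.11, and the receptors Gpr84 and Gpr132 each 4.10.

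**Figure D1:**
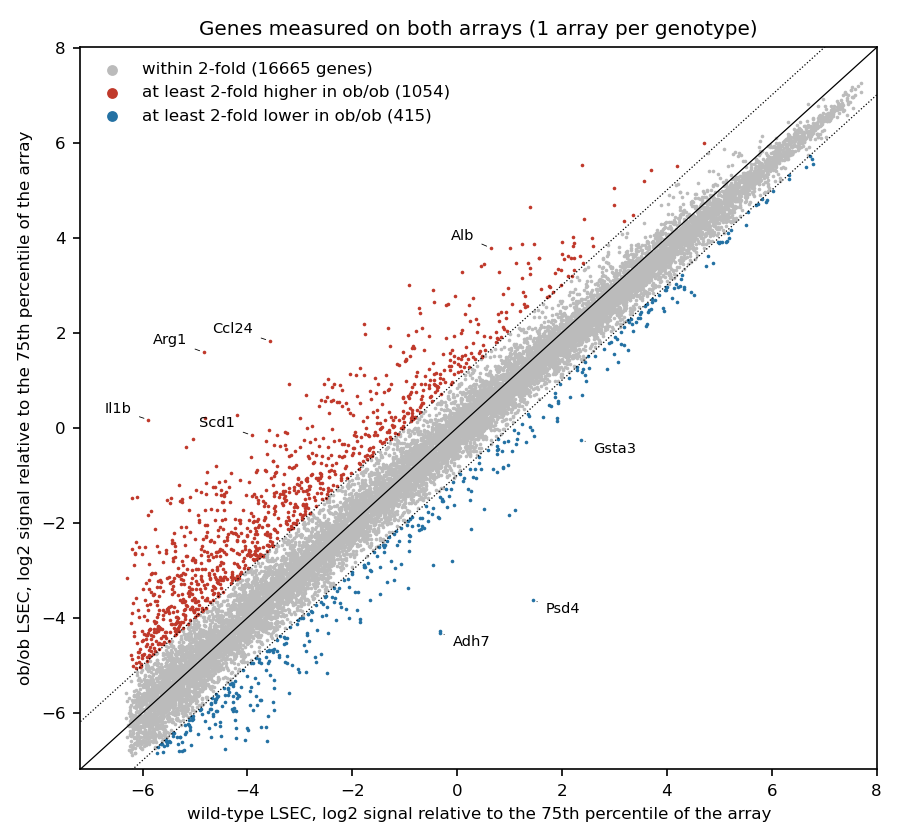
Log2 signal relative to the 75th percentile of the array in wild-type (x axis) and ob/ob (y axis) LSEC, 1 point per gene measured on both arrays and 1 array per genotype. The solid line marks equal values and the dotted lines 2-fold, with 1054 genes above the upper and 415 below the lower dotted line. Psd4 lies in the bright patch of the wild-type array and has a difference of -5.08.

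The lower side held smaller differences. The largest of the named genes by value was Psd4 at -5.08, whose spot on the wild-type array lies in a patch of bright spots, as does that of the serotonin receptor Htr7 at -2.17. Outside the patches, the alcohol and retinol dehydrogenase Adh7 was lower at -4.00 (signals 787 and 71.1, chromosome 3, 137894495 to 137894554) and the amino acid transporter Slc38a7 at -3.95 (signals 792 and 74.0, chromosome 8, 98360074 to 98360133). The activin antagonist Fst was lower at -2.83, Rnf183 at -2.71, Hfm1 at -2.68 and the glutathione transferase Gsta3 at -2.63. The growth factor Nrg1 at -2.43, the actin-severing protein Scin at -2.40, Sowahb at -2.25 and the metalloprotease Mep1a at -2.25 complete the 12.

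Markers of endothelial identity stood close to the median of all genes, which was -0.12. The sinusoidal endothelial list had a median of -0.18 (-0.32 to 0.06, percentile 46.0, 0.06 after centring on the level), with 27 of 28 members within 2-fold and 1 lower, Adam23 at -1.77. The scavenger receptors Stab2 and Stab1 differed by -0.18 and -0.36, and Lyve1 by -0.40. The pan-endothelial list had a median of -0.19 (-0.36 to 0.12, percentile 85.2, 0.06 after centring on the level), with 29 of 30 members within 2-fold. Its exception was the transcription factor Sox18, 1.35 higher. The junction proteins Cdh5 and Pecam1 differed by -0.44 and 0.12. Pericentral endothelial markers had a median of 0.00 (-0.46 to 0.47, percentile 95.4), with 1 of 10 members lower, Ramp3 at -1.03, and the median was 0.23 (percentile 99.2) with quantile normalization and -0.28 with scaling on the array median.

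Other endothelial lists had some members at least 2-fold higher, and most within 2-fold. The periportal list had a median of 0.75 (0.18 to 2.36, percentile 99.97), with 4 of 10 members at least 2-fold higher and 6 within 2-fold, or a median of 0.22 and 2 higher with normexp and the 75th percentile. The Notch ligand Dll4 was 2.28 higher, the arterial connexin Gja5 2.08, the adhesion receptor Adgrg6 2.36 and the scavenger receptor Msr1, which macrophages express too, 2.63. The list for capillarization, the change of sinusoids towards continuous capillaries with a basement membrane, had a median of 0.38 (-0.08 to 1.17, percentile 100), with 8 of 24 members higher, 0 lower and 16 within 2-fold. The capillarization median was 0.10 with scaling on the array median and 0.12 with normexp and the 75th percentile, with 5 higher in each and 1 lower in the latter. Among the 8 were the basement membrane proteins Nid2 at 1.58 and Lamb1 at 1.52, Fbln2 at 1.85, von Willebrand factor Vwf at 1.44 and the diaphragm protein Plvap at 1.17. Of leukocyte adhesion genes, 5 of 18 were higher, 1 lower and 12 within 2-fold (median 0.13, -0.36 to 1.21, percentile 99.9, and -0.15 with scaling on the array median). P-selectin Selp was 3.24 higher, E-selectin Sele 2.34, the chemokine-binding receptor Ackr1 2.81 and Icam1 1.21, while Vcam1 at 0.60 was within 2-fold and Madcam1 was lower at -1.48. On the same array the macrophage and the stellate cell list each had a median of 1.51 and the hepatocyte list of 2.40.

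The cytokine and chemokine list had a median of 1.32 (0.69 to 1.98, percentile 100), with 19 of 34 measured members at least 2-fold higher, 0 lower and 15 within 2-fold. The cytokine median was 0.91 with 16 higher under normexp with quantile normalization and 0.82 with 14 higher and 2 lower under normexp and the 75th percentile. On the same array the macrophage list had a median of 1.51 with 20 of 27 higher. After Il1b and Ccl24, the largest were the chemokine Ccl9 at 3.93 and the cytokine Il18 at 3.68, and Il6 at 3.08, not among the 4 largest, was looked at after its value was seen. The acute-phase protein Saa3 was at least 19.7-fold, the cytokine Il10 at least 6.16-fold and the prostaglandin synthase Ptgs2 at least 5.43-fold brighter on the ob/ob array, being not well above background in wild-type cells. NF-kB target genes had a median of 0.37 (-0.09 to 0.73, percentile 100, and 0.10 with 1 higher and 1 lower with scaling on the array median), with 2 of 18 higher, Cd83 at 1.57 and Icosl at 1.23, and the inhibitor Tnfaip3 at -0.87. Antigen presentation genes had a median of 0.54 (0.16 to 1.07, percentile 100), with 8 of 22 higher, or 5 with normexp and quantile normalization and 3 with scaling on the array median, led by the costimulator Cd86 at 2.99 and the class II accessory chains H2-DMa at 2.48 and H2-DMb1 at 2.25. Interferon response genes had a median of 0.02 (-0.16 to 0.25, percentile 100, 97.0 against random lists not matched on level, and -0.26 with scaling on the array median), with 5 of 41 higher, 1 lower and 35 within 2-fold. They included Mx1 at 2.14, Oas3 at 1.73 and Gbp6 at -1.38, of which a second probe gave 1.08.

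Most macrophage markers were higher. The Kupffer cell and macrophage list had a median of 1.51 (1.002 to 1.95, percentile 100), with 20 of 27 members at least 2-fold higher, 1 lower and 6 within 2-fold, against 17 higher with a median of 1.09 under normexp and the 75th percentile. Besides Timd4, the cytoplasmic marker Aif1 was 3.96 and the complement receptor Vsig4 3.20 higher, and the iron exporter Slc40a1 was lower at -1.71. The 3 brightest members of the list had a median difference of 1.29. Of markers of lipid-associated and monocyte-derived macrophages, 3 of 13 were higher and 0 lower (median 0.49, -0.33 to 1.11, percentile 100, and 0.21 with 2 higher and 1 lower with scaling on the array median), with osteopontin Spp1 at 3.73, the integrin Itgax at 3.54 and Lpl at 1.11, and the chitinase-like Chil3 at least 110-fold brighter on the ob/ob array. The 3 brightest members of that list had negative differences, Ctsd at -0.97, Cd63 at -0.41 and Lgals3 at -0.33, and after centring on the level these were -0.53, 0.06 and 0.07.

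Most hepatocyte and stellate cell markers were higher as well. Of hepatocyte markers 21 of 25 were at least 2-fold higher, 0 lower and 4 within 2-fold (median 2.40, 2.02 to 2.83, percentile 100), against 16 higher and 2 lower with a median of 1.61 under normexp and the 75th percentile. They included the cytochrome Cyp3a11 at 3.79, the apolipoproteins Apob at 3.65, Apoc3 at 3.36 and Apoh at 3.17. Albumin, Alb, among the 3 brightest members, was 3.15 higher. The gluconeogenic enzymes G6pc and Pck1 were at least 3.05-fold and 2.84-fold brighter on the ob/ob array. Of stellate cell and fibroblast markers, 18 of 22 were higher, 0 lower and 4 within 2-fold (median 1.51, 1.18 to 2.05, percentile 100), against 11 higher with a median of 1.004 under normexp with quantile normalization and 7 with a median of 0.64 under normexp with the 75th percentile. They included Col3a1 at 2.92, Timp1 at 2.47 and the retinol-esterifying enzyme Lrat, chosen after its value was seen, at 2.32. Col1a1 was at least 8.12-fold brighter on the ob/ob array. Cholangiocyte markers had 3 of 6 higher (median 1.89, -0.43 to 3.73, percentile 100), the keratins Krt8 at 2.90 and Krt18 at 2.81 and Spp1, and 6 more were measured on the ob/ob array only. With those at their bounds the cholangiocyte median was 0.77, and with normexp and the 75th percentile it was 0.19 with 3 higher and 2 lower. Lymphocyte markers had 0 of 8 beyond 2-fold (median 0.20, -0.22 to 0.87, percentile 86.7, -0.08 with scaling on the array median, and -0.66 with 3 lower under normexp and the 75th percentile). With members measured on at least 1 array, their background-level signals taken as they stand, the lymphocyte median was 0.64 (percentile 98.3), with 7 of 16 higher and 0 lower. Of these, 8 were measured on the ob/ob array only, among them the granzyme Gzmb at least 8.80-fold and Cd3d at least 6.44-fold. With those 8 at their bounds the lymphocyte median was 0.29. Neutrophil markers had 1 of 7 higher, Lcn2 at 2.28, and 2 lower, Mpo at -1.32 and Elane at -1.01 (median -0.24, -1.32 to 2.28, percentile 13.7, and -1.30 with 5 of 7 lower and percentile 0.29 under normexp and the 75th percentile). With members measured on at least 1 array, taken in the same way, the neutrophil median was 0.08 (percentile 49.7), with 5 of 13 higher and 3 lower. With members measured on 1 array at their bounds it was -0.06. Mmp8 and S100a9 were at least 9.30-fold and 5.77-fold brighter on the ob/ob array. Erythroid markers had a median of 0.04 (-0.42 to 1.11, percentile 65.2, -0.24 with scaling on the array median, and -0.85 with 2 lower under normexp and the 75th percentile) with 1 of 6 higher, Car2 at 1.11. Of adipocyte and mesothelial markers 1 was measured on both arrays, Gpm6a at 0.64, and -0.09 with normexp and the 75th percentile. In all, 66 of 114 measured genes of these 9 lists of other cells were at least 2-fold higher and 3 lower. Of all 18134 genes measured on both arrays, 1054 were higher and 415 lower. The lists are short, so they do not tell how many of the 1054 come from other cells.

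**Figure D2:**
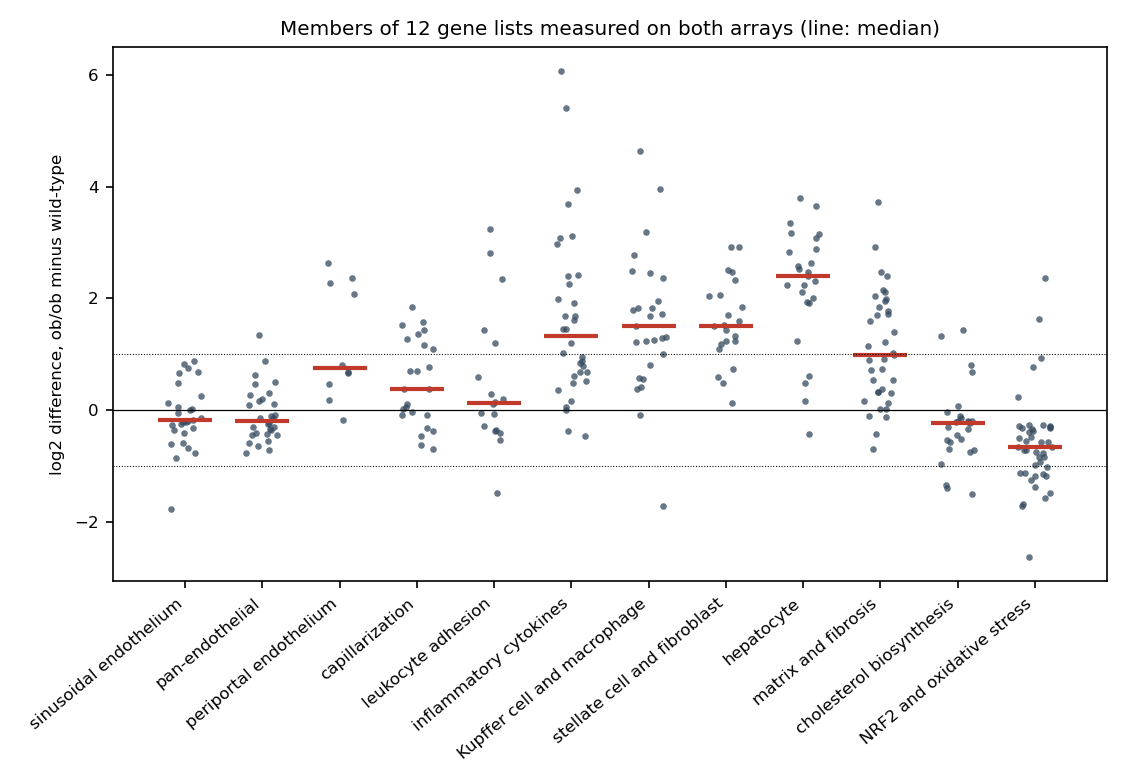
Log2 difference, ob/ob minus wild-type, for each member of 12 gene lists measured on both arrays, with the red line at the median of the list and the dotted lines at 2-fold. The sinusoidal and pan-endothelial medians lie at -0.18 and -0.19 (both 0.06 after centring on the level), the macrophage, stellate cell and hepatocyte lists lie mostly above the upper dotted line, and most NRF2 genes lie below 0.

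Medians of matrix and mesenchymal lists had the same sign as that of the stellate cell markers, 1.51. The matrix and fibrosis list had a median of 0.99 (0.54 to 1.71, percentile 100), with 18 of 37 members higher, 0 lower and 19 within 2-fold, or 8 higher and 1 lower with normexp and the 75th percentile. Spp1, Col3a1 and Timp1, shared with the lists above, and fibronectin Fn1 at 2.40 were its largest. The endothelial-to-mesenchymal transition list had a median of 1.38 (0.26 to 1.98, percentile 100), with 11 of 19 higher, 1 lower and 7 within 2-fold, or a median of 0.44 and 8 higher with normexp and the 75th percentile. S100a4 was 3.83, smooth muscle actin Acta2 2.42 and Fn1 2.40 higher. The lower member was the transcription factor Snai2 at -2.82, which lies in the bright patch of the wild-type array. It was 3.005 higher under normexp correction with quantile normalization. That correction subtracts the local background, which was 3125 at this wild-type spot beside a processed signal of 2112. The direction for Snai2 is therefore not settled. TGF-beta and BMP genes had 5 of 25 higher and 1 lower, the antagonist Fst (median 0.44, -0.14 to 0.64, percentile 100, and 0.08 with 1 higher and 2 lower under normexp and the 75th percentile), with the ligands Tgfb3 at 2.72, Tgfb2 at 2.19 and Inhba at 1.97.

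Genes of vascular tone had 11 of 34 members higher, 0 lower and 23 within 2-fold, or 4 and 0 with normexp and quantile normalization and 4 and 2 with normexp and the 75th percentile (median 0.28, -0.05 to 1.04, percentile 100, and -0.003 with scaling on the array median), beside medians of 1.51 in both the stellate cell and the macrophage list. The endothelin receptor Ednra was 2.82 higher, thromboxane synthase Tbxas1 2.80 and the guanylate cyclase subunits Gucy1b3 and Gucy1a3 2.14 and 2.03, and Cyp1b1 was at least 18.9-fold brighter on the ob/ob array. The nitric oxide synthase Nos3, looked at after its value was seen, differed by 0.17. Coagulation genes had 9 of 20 higher and 0 lower (median 0.81, -0.25 to 1.64, percentile 100, and 0.007 with 4 higher under normexp and the 75th percentile). These included F7 at 3.01, Serpinc1 at 2.95 and Proc at 2.10, which hepatocytes secrete, beside a hepatocyte list median of 2.40. Notch genes had 3 of 15 higher, Dll4, Jag1 at 1.39 and Hey1 at 1.08, and 1 lower, Notch1 at -1.10 by its brighter probe and 0.41 by the other (median 0.34, -0.16 to 0.96, percentile 99.9). The Notch median was 0.04 (percentile 96.9, inside the central 95%) with normexp and the 75th percentile, and 0.06 with 2 higher and 2 lower with scaling on the array median. Wnt and angiocrine genes had 7 of 21 higher (median 0.43, -0.08 to 1.16, percentile 100, and -0.29 at percentile 56.2 with normexp and the 75th percentile), with Igfbp5 at 2.49, Igfbp3 at 2.37 and the growth factors Pdgfb at 1.93 and Vegfa at 1.75.

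Lipid genes differed in both directions. Of lipid uptake and storage genes 4 of 31 were higher, 1 lower and 26 within 2-fold (median 0.20, -0.04 to 0.49, percentile 100, and -0.08 with scaling on the array median). The counts were 1 higher and 3 lower with that scaling and 3 higher and 6 lower with normexp and the 75th percentile. The lipoprotein lipase inhibitor Angptl4 was 3.27 higher, Lpl and Apold1 each 1.11 higher, and the phosphatidate phosphatase Lpin1 was lower at -1.45. Of lipogenesis genes 4 of 21 were higher and 0 lower (median -0.07, -0.46 to 0.54, percentile 53.7, 0.00 after centring on the level). The lipogenesis median was -0.35 with 2 higher and 2 lower under normexp and the 75th percentile, and -0.24 (percentile 4.78) above 4 times the dimmest measured signal. The 4 were the desaturases Scd1 at 3.76 and Scd2 at 1.65, Thrsp at 3.13 and the elongase Elovl6 at 1.37, while fatty acid synthase Fasn, looked at after its value was seen, differed by -0.07. Cholesterol biosynthesis genes had a median of -0.24 (-0.56 to -0.14, percentile 1.28), with 2 of 27 higher, 3 lower and 22 within 2-fold, or 0 higher and 7 lower with normexp and the 75th percentile. Among the lower ones were Idi1 at -1.39 and Sqle at -1.34. Against random lists not matched on level the percentile was 7.20. LXR and sterol efflux genes had 2 of 13 higher, the sterol receptor Nr1h3 at 2.10 and Pltp at 1.62 (median 0.32, -0.35 to 0.83, percentile 99.99, and 0.04 with scaling on the array median), and 1 was lower with normexp and the 75th percentile. Fatty acid oxidation genes had 4 of 26 higher and 1 lower (median 0.12, -0.09 to 0.48, percentile 99.7, 94.5 above 4 times the dimmest measured signal, and -0.16 with scaling on the array median), with Acot2 at 1.66, Acot1 at 1.53, Cpt1a at 1.15 and Acads at -1.03, and the fatty acid hydroxylase Cyp4a14 at least 56.6-fold brighter on the ob/ob array. Hepatocytes express several of these genes, and their markers had a median of 2.40.

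Glycolysis and hypoxia genes had 9 of 35 members higher, 0 lower and 26 within 2-fold (median 0.40, 0.14 to 0.90, percentile 100), beside medians of 1.51 in the macrophage and the stellate cell list and 2.40 in the hepatocyte list. The glycolysis median was 0.12 with scaling on the array median, and 7 members were higher with either normexp setting. The lactate exporter Slc16a3 was 2.81 higher, aldolase Aldoc 2.61, Tpi1 1.90 and Vegfa 1.75. Of targets of NRF2, the transcription factor of the antioxidant response, with other oxidative stress genes, 13 of 43 were at least 2-fold lower, 2 higher and 28 within 2-fold (median -0.67, -0.93 to -0.40, percentile 0). The counts were 7 lower and 4 higher after centring on the level and with normexp and quantile normalization, and 8 and 4 with quantile normalization. Gsta3 was lowest, followed by the glutathione synthesis subunit Gclm at -1.71 and the transporter Abcc4 at -1.69. The quinone reductase Nqo1 at -1.49 and haem oxygenase Hmox1 at -1.18 were looked at after their values were seen. The higher pair were Cybb at 2.37, the phagocyte oxidase subunit also on the macrophage list, and Sod3 at 1.63, and Gpx3 was at least 5.34-fold brighter on the ob/ob array. The p53 and senescence list had a median of -0.55 (-0.71 to -0.26, percentile 0), with 4 of 25 lower, 1 higher and 20 within 2-fold. After centring on the level its median was -0.36, and with normexp and quantile normalization -0.32, with 1 lower in each. The cell cycle inhibitors Cdkn2a, whose other probe gave -0.59, and Cdkn2b were lower at -1.46 and -1.07, Gdf15 at -1.09 and Phlda3, chosen after its value was seen, at -1.05. Igfbp3 was the higher one, and Cdkn1a differed by 0.00.

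**Figure D3:**
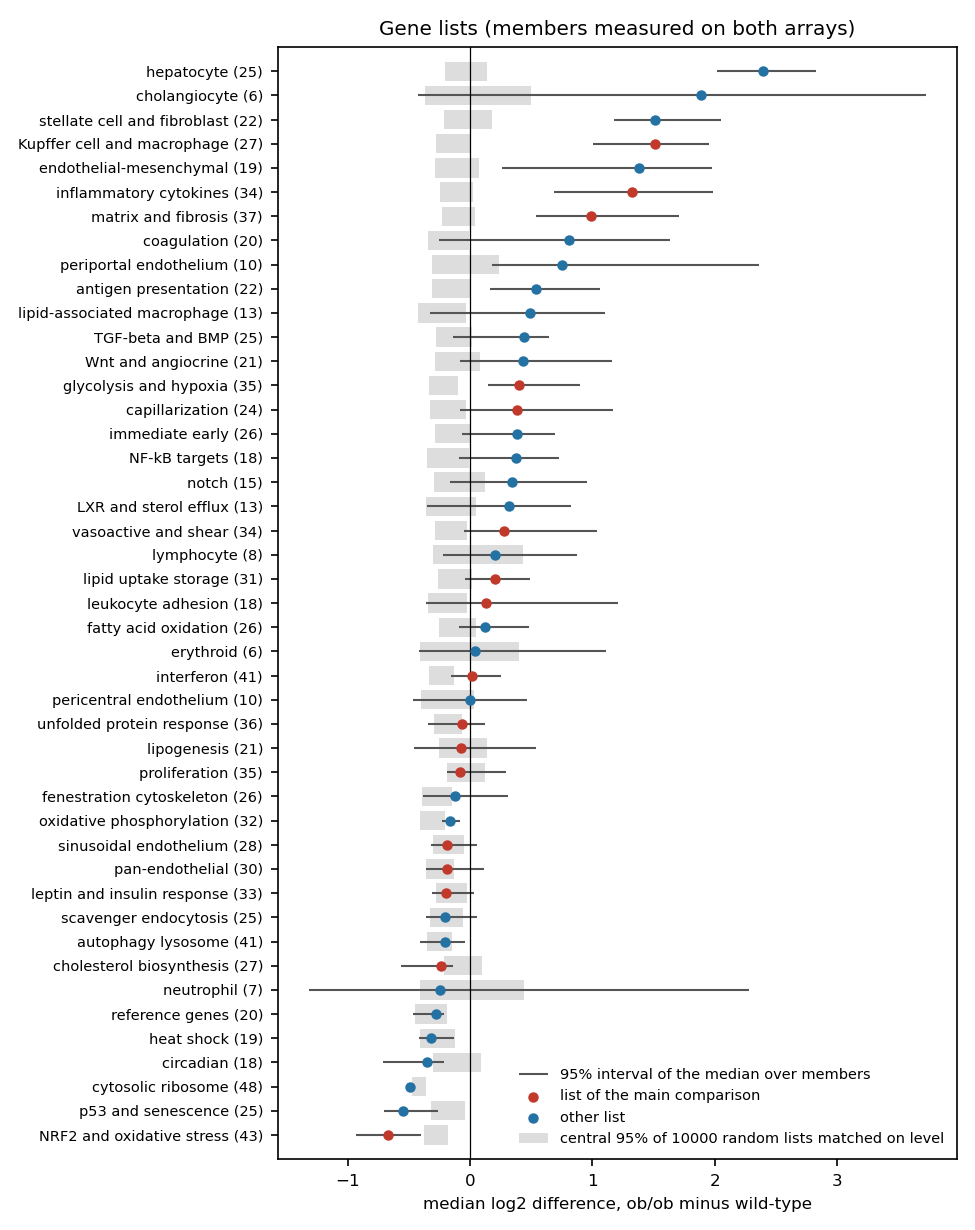
Median log2 difference, ob/ob minus wild-type, of the 45 gene lists with at least 5 measured members (points, the number measured in brackets), with its 95% interval over members (lines) and the central 95% of 10000 random lists matched on level (grey bars). The hepatocyte list stands highest at 2.40 and the NRF2 list lowest at -0.67.

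The unfolded protein and integrated stress response list had a median of -0.07 (-0.34 to 0.12, percentile 97.6, 78.5 against random lists not matched on level, and 0.17 after centring on the level), with 1 of 36 higher, Nupr1 at 1.47, and 1 lower, the asparagine synthetase Asns at -1.18. Heat shock genes had a median of -0.32 (-0.41 to -0.13, percentile 24.6, and 1.70 against random lists not matched on level), with 1 of 19 higher, Hspb8 at 1.81. The heat shock median was -0.04 after centring on the level and -0.60 with scaling on the array median. Immediate early genes had 6 of 26 higher and 0 lower (median 0.38, -0.07 to 0.70, percentile 100, and 0.10 with 3 higher and 1 lower with scaling on the array median), with Ccn1 at 1.41 and Junb and Dusp2 at 1.40. Beside them, the macrophage and stellate cell lists had medians of 1.51 and the hepatocyte list of 2.40. Proliferation genes had 0 of 35 higher and 1 lower, the kinesin Cenpe at -1.24 (median -0.08, -0.19 to 0.29, percentile 33.5, 0.09 after centring on the level, and -0.68 with 7 lower under normexp and the 75th percentile), and Tk1 was at least 10.7-fold brighter on the ob/ob array.

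Among genes measured on 1 array only, 422 of 2168 were at least 2-fold brighter on the ob/ob array and 197 of 270 on the wild-type array. These counts are not on the same footing. The dimmest measured log2 signal, relative to the 75th percentile, was -6.32 on the wild-type and -6.93 on the ob/ob array. A gene measured on the wild-type array only therefore reaches a bound at a lower scaled signal. At 1.5-fold the counts were 651 of 2168 and 270 of 270. The largest bounds on the ob/ob side were Chil3 at 110-fold, the ubiquitin ligase Mid1 at 72.8-fold (chromosome X, 166428452 to 166428511), Cyp4a14 at 56.6-fold, and the leukocyte genes Ms4a4a at 33.2-fold, Cd300e at 28.7-fold and Cytip at 27.3-fold. On the wild-type side D15Ertd55e reached at least 11402-fold, the Y-linked deubiquitinase Usp9y 1961-fold, the regenerating protein Reg2 1234-fold, Rgs8 43.4-fold, Fam155a 16.2-fold and Fbxw14 15.03-fold. Of these 6, all but Fam155a lie in patches of spots that are brighter on the wild-type array than their surroundings. The larger patch holds 46 spots in rows 521 to 532 and columns 29 to 34, and the smaller 29 spots in rows 106 to 117 and columns 1 to 3. Without the spots of both patches, the wild-type side kept 176 genes with a bound of at least 2-fold, and those of at least 8-fold went from 25 to 11, while the ob/ob side stayed at 422 and 57.

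**Figure D4:**
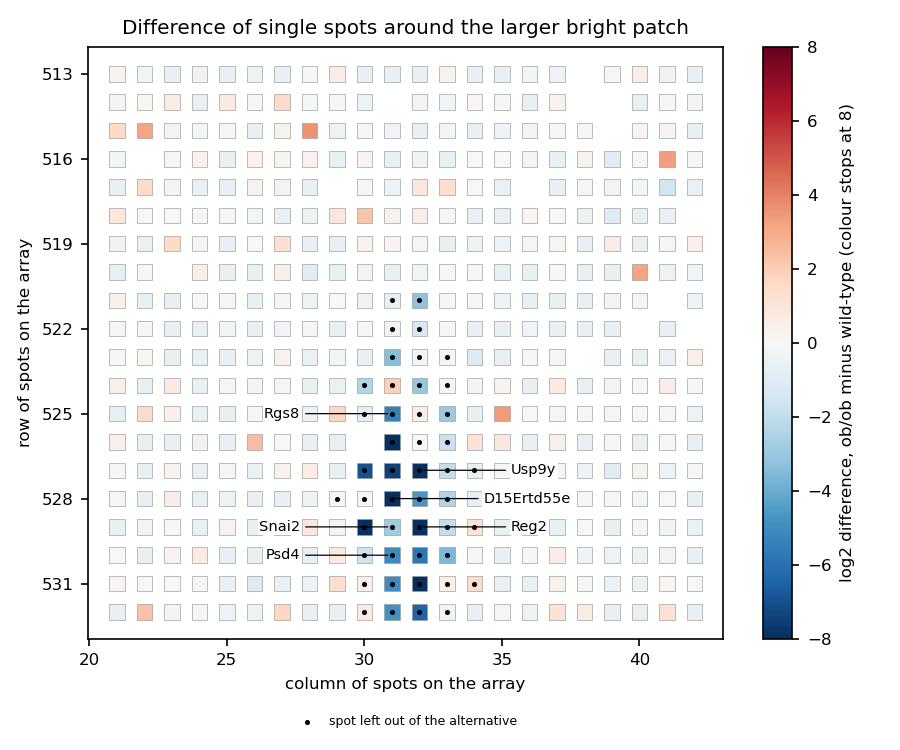
Log2 difference, ob/ob minus wild-type, of single non-control spots at the lower edge of the array, by column and row, with signals below the dimmest measured one raised to it. Blue spots have negative differences. Spots below the dimmest measured signal on both arrays read -0.61, the gap between those dimmest signals. They show as blue too without being brighter on the wild-type array. Black dots mark the 46 spots left out without the patch, and Usp9y, D15Ertd55e, Reg2, Psd4, Snai2 and Rgs8 lie within it.

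In the brightest of 4 equal groups of genes by signal level the median was -0.29 and in the dimmest -0.01. In place of 1054 higher and 415 lower genes, scaling on the array median gave 765 and 976, and normexp with the 75th percentile 368 and 3818. Scaling on the array median moves every difference by the same -0.28. Counted from the median of all genes, the numbers were 1204 and 286 both before and after that scaling. With normexp and the 75th percentile they were 578 and 2380. With normexp and the 75th percentile 10 of the higher genes named above had negative values: Adgrg6, Gja5, Fbln2, H2-DMa, Thrsp, Pltp, Acot2, Aldoc, Tgfb2 and F7. Of these, only Fbln2, H2-DMa and Acot2 lay below the median of all genes in that setting, -0.29. The mean of the other measured probes had the same sign in 121 of 134 higher genes (90.3%) and in 55 of 68 lower genes (80.9%). That mean was itself at least 2-fold in the same direction in 94 of the 134 higher genes. Among the 68 lower genes it was so in only 24.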

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

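All tests below were chosen after results were seen. For the 2 of the median local background the prediction was written before those tests, but after the reversal of Snai2 had been seen. Their reading by the number of spots above the 99th percentile was chosen, and changed more than once, afterwards. A control probe, 1 of 18 of its kind (DCP), read well above background on the ob/ob array only, with a median signal of 12.4 where the dimmest measured gene had 11.7.

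The genes brightest on the wild-type array and not above background on the ob/ob array lay next to each other. Of the 25 with a bound of at least 8-fold, 15 had another of them among their 12 nearest spots, against at most 6 in 10000 random draws (ob/ob array: 4 of 57, highest draw 8). This restates the patches, which were found from the differences of neighbouring spots and hold 14 of the 25, so it tests no cause. A raised local background had been predicted, after the reversal of Snai2 had been seen, and the prediction failed: the median was 1.01 times that of the array around the 14 spots inside the patches and 1.02 around the 11 outside. That bound on the median was wrong, since a median misses brightness around the smaller part of the spots: 5 of the 14 inside and 2 of the 11 outside exceeded the 99th percentile of the array, where 0.14 and 0.11 would by chance, with highest values of 52.8 and 1.13 times the median. Stray brightness therefore stays open for both sets as a whole. The local background was raised around those 5 spots inside the patches, up to 52.8 times the array median. Around the spots outside it reached at most 1.13 times. Snai2, measured on both arrays and in the larger patch, had a background of 3125 where the ob/ob array had 56. For Usp9y a loss of Y-linked transcripts is argued against by 3 other Y-linked genes, with a median difference of 0.59 (Ddx3y -0.21, Uty 0.59 with its other probe at -0.38, Eif2s3y 0.72), and the genotype stays untested.

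The medians of the macrophage, stellate cell and hepatocyte lists were all higher on the ob/ob array. A lower share of endothelial cells, with all other cells in wild-type proportions, would raise them alike if endothelial cells expressed none of the markers. They did not rise alike. Their medians spread over 0.89, and the interval of the hepatocyte list (from 2.02) lay just above that of the macrophage list (to 1.95). These intervals hold only the spread over members, and expression of the markers by endothelial cells was not tested. The explanation therefore stays open. More RNA of each cell type by its own factor would raise the brightest members too. The 3 brightest members of each list had medians of 2.64 (hepatocyte), 2.05 (stellate cell) and 1.29 (macrophage). They belong to the lists already seen to be higher, and a change within the cells could raise them as well. This outcome therefore cannot decide, and that explanation stays open too. No sort or gate is named in the labels. A change of expression within these cells, and the genotype itself, were not tested and stay open.

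The median of the NRF2 targets was lower on the ob/ob array. The fall of differences with signal level is argued against as the whole cause, since after centring on the level the median was -0.35, below all 10000 random lists, though it had been -0.67. Dilution of endothelial RNA is argued against as the whole cause, because the NRF2 median lay at -0.48 from the lower endothelial median of -0.19 and its interval ended at -0.40. The genotype, and differences between the 2 preparations or cultures, may each be the source and were not tested.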

How the results depend on the processing

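Leaving out the patches was chosen after seeing the data; the other alternatives were fixed before. No paired analysis was possible because each group holds 1 array. Signal over background limits the dim genes, and 11298 genes were measured on neither array. The cause was not tested where none is given. The median of all genes shifted by -0.28 with scaling on the array median, by -0.17 with another background correction (normexp, scaled as before) and by 0.13 with centring on the level, and differences are read relative to these. The share of higher genes among those 2-fold apart was 71.7%, and 43.9% with the array median and 8.79% with normexp and the 75th percentile.

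The counts of 1054 higher and 415 lower genes became 507 and 130 with normexp and quantile normalization, 368 and 3818 with normexp and the 75th percentile, and 2148 and 667 when genes measured on at least 1 array entered, the last by construction. With the array median 976 were lower. Above 4 times the dimmest measured signal 644 were higher, from fewer genes. At 1.5-fold the counts were 1777 and 1649, and at 3-fold 543 and 91. Without the patches they were 1053 and 407, all among the genes counted before. The number of genes measured on 1 array only with a 2-fold bound was 619, or 1446 with the other background flag and 213 at a 4-fold bound.

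With the array median, list medians became -0.46 (sinusoidal), -0.47 (pan-endothelial), 0.12 (glycolysis), -0.36 (proliferation), -0.34 (unfolded protein), -0.95 (NRF2) and -0.48 (leptin and insulin), and turned negative for leukocyte adhesion (-0.15), interferon (-0.26), lipid uptake (-0.078), fatty acid oxidation (-0.16) and vascular tone (-0.0030). Centring on the level gave 0.060 (sinusoidal), 0.26 (interferon), -0.35 (NRF2) and, turned, 0.17 (unfolded protein), 0.080 (fenestration and cytoskeleton) and 0.13 (oxidative phosphorylation). With normexp and quantile normalization NRF2 was -0.36, and unfolded protein (0.045), fenestration (0.14) and oxidative phosphorylation (0.065) turned. With quantile normalization NRF2 was -0.38, and unfolded protein (0.11), fenestration (0.073) and oxidative phosphorylation (0.10) turned. With normexp and the 75th percentile cholesterol was -0.63, matrix 0.45 and proliferation -0.68, and oxidative phosphorylation (0.0009) and Wnt and angiocrine (-0.29) turned; the lymphocyte (-0.66) and erythroid (-0.85) medians, inside the central 95% of their random lists before, fell below 0 and the neutrophil median fell to -1.30. Above 4 times the dimmest measured signal interferon (-0.0018) and fatty acid oxidation (-0.0004) turned, and with the mean of probes fenestration did (0.0034). Without the patches no list median left its interval. With members measured on 1 array at their bounds the medians were 2.31 (hepatocyte), 1.31 (macrophage), 1.47 (stellate cell), 1.45 (cytokine) and 1.004 (matrix).

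With normexp and the 75th percentile, genes that were higher turned to -0.28 (Adgrg6), -0.26 (Gja5), -0.30 (Fbln2), -0.41 (H2-DMa), -0.12 (Thrsp), -0.24 (Pltp), -0.86 (Acot2), -0.047 (Aldoc), -0.22 (Tgfb2) and -0.17 (F7). Snai2 turned to 3.005 with normexp and quantile normalization and to 2.63 with normexp and the 75th percentile, its local background being subtracted there. Of the 201 named genes left without the patches, 0 moved by more than their error. This follows from the construction, since only patch spots were removed and the scaling was kept. Of 204 named genes, 190 moved by more than their error with the array median, which shifts all alike. With normexp and quantile normalization 140 moved and 1 reversed, and with normexp and the 75th percentile 108 moved and 11 reversed. Quantile normalization moved 48, centring on the level 45 and the mean of probes 20.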

Other observations

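All 48 cytosolic ribosomal proteins had negative differences, with a median of -0.49 (-0.51 to -0.45, percentile 0.84). The median was -0.02 with normexp and quantile normalization (percentile 47.9), -0.03 with quantile normalization and -0.04 after centring on the level. Rps6 was lowest at -0.71 by its brightest probe, while another gave 0.09. With the mean of all probes of a gene the percentile was 41.7. Oxidative phosphorylation genes had a median of -0.16 (-0.23 to -0.08), with -0.30 in their random lists (percentile 99.7). The percentile was 96.8 with normexp and quantile normalization and 28.0 against random lists not matched on level. The median was 0.0009 with normexp and the 75th percentile and 0.13 after centring on the level, with 0 of 32 beyond 2-fold. Reference genes had a median of -0.28 (-0.46 to -0.21, percentile 74.6, and 0.03 with normexp and quantile normalization), with 0 of 20 beyond 2-fold and Tubb5, a tubulin, at -0.86.

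Clock genes had a median of -0.35 (-0.71 to -0.21, percentile 0.74), with 2 of 18 higher and 2 lower, or 0 and 0 with normexp and quantile normalization and 0 and 6 (median -0.58) with normexp and the 75th percentile. The activator Arntl was 1.54 higher, the repressor Bhlhe40, with signals of 544 and 1690, was higher as well, and Bhlhe41 and the clock output factor Tef were lower at -2.38 and -1.22. Scavenger and endocytosis genes had a median of -0.21 (-0.36 to 0.06, percentile 41.2, and 0.04 after centring on the level), with Msr1 at 2.63, Lrp1 at 1.94 and Marco at 1.29 the 3 of 25 higher, and 1 was lower. Fenestration and cytoskeleton genes had a median of -0.12 (-0.39 to 0.31, percentile 98.9, 48.9 against random lists not matched on level, and 0.08 after centring on the level), with 2 of 26 higher, Myl9 at 1.98 and Plvap. Autophagy and lysosome genes had a median of -0.21 (-0.41 to -0.04, percentile 78.2, and 0.04 after centring on the level), with 2 of 41 higher, Bnip3 at 1.41 and Lipa at 1.02.

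Within the hepatocyte list Mup3, a major urinary protein, differed by -0.42 while the median was 2.40. Without the patches the largest bounds on the wild-type array were Fam155a at 16.2-fold, D18Ertd734e at 12.1-fold, Art2a at 11.4-fold, Heatr7b1 at 10.1-fold, Cldn4 at 9.58-fold and Lrmda at 9.37-fold, and Kdm7a at -2.17 and Erv3 at -2.11 entered the 12 largest lower differences in place of Psd4 and Htr7.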
